A study of Mus musculus with 4 samples.

How the data were processed

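RNA from AML12, an established mouse hepatocyte line, was compared in 4 polyA-selected Illumina libraries, 2 from cells transfected with a GFP control plasmid (pCMV6-AC-GFP, replicates 1 and 3) and 2 from cells transfected with a plasmid carrying Chrna4 (PAV-TBG-P2A-GFP-Chrna4, replicates 1 and 2), per the labels' protocols. Libraries were grouped by the plasmid the labels give. The labels do not say whether replicates were separate cultures or transfections, so the p-values measure only the spread between these samples, which may be technical. TopHat2 and HTSeq are named, without versions or settings, together with mm10/GRCm38 in the submitters' processing notes. Whether counting used strand is not given in the sources used here.

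The authors deposited 1 table of 13422 genes, each with a symbol and an Ensembl identifier. Per the file headers it holds 1 value per gene and library and the authors' own comparison, with a log2 fold change, a log2 mean CPM, a p-value and an adjusted p-value. The tool behind that comparison is not given in the sources used here, and its log2 fold change, deposited as control over Chrna4, was turned round so that a positive value means higher in Chrna4. The deposited per-library signal is a CPM value relative to a scaled library size, since the columns sum to different totals, from 978506 to 1020160. In each column 100% of the deposited CPM values were whole multiples of 1 step within a tolerance of 0.01 reads, so the whole reads could be recovered. Scaling factors recomputed from those reads by the TMM method differed from the deposited scaling by a relative 6.7e-16 at most. The lowest total over the 4 libraries of any listed gene was 10 reads, and the rule behind that filter is not given in the sources used here.

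Listed genes received 31968119 reads in Control 1, 31669041 in Control 3, 31301396 in Chrna4 1 and 32228360 in Chrna4 2. A single read was worth 0.0308, 0.0309, 0.0325 and 0.0317 CPM in the same order. Intervals given for read counts are exact 95% intervals and cover counting error only, since reads without molecular identifiers are not independent molecules.

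The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(CPM + 1) over the 11298 genes with a mean of at least 1 CPM, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Fold changes from this fit are on the log2(CPM + 1) scale, which understates the change of low genes. The fit had 2 residual degrees of freedom per gene and borrowed 9.55 prior degrees of freedom from the other genes. Gene lists, 30 in all with 754 entries, were written before the data were examined, as were the design, the alternatives and the rule for naming genes. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01. They were tested again with an estimated correlation and with fry. Fry asks whether a list's genes move 1 way on balance and compares the list with no other genes. With an estimated correlation camera is left with the 2 residual degrees of freedom of the fit, so a list can fail there without correlated genes. List members were matched by symbol in the deposited table or in the GENCODE M21 annotation of GRCm38, in which 98.9% of the identifiers were found. That annotation supplied coordinates, GC content and transcript length.

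Genes are named by this rule: Chrna4; the 12 largest changes in each direction among genes past the threshold with a mean of at least 5 CPM, a named symbol and no overlap between the groups' libraries; the 6 called genes of highest level that changed by at least 1.5-fold; and from each list up to 4 called members of smallest adjusted p, or where fewer than 2 were called, up to 2 of highest level as values only. Any gene named outside it is said to be chosen after its values were seen, and some genes that the rule takes are not reported here.

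The alternatives were RLE factors, library totals, no filter, a minimum of 5 CPM, a pseudocount of 0.1, each library left out, a stricter threshold, and on the recovered reads limma-voom, DESeq2 1.42.0 and edgeR 4.0.16 without robust estimation. The robust edgeR quasi-likelihood test on recovered reads, a correction for GC content and transcript length, and the pseudocount of 0.1 for the lists were added after the data had been seen. Because the deposited values were not raw counts, the count test stood as an alternative and not as the main test. The fit was tested on reads simulated with the real means and library sizes, each gene drawn independently with 1 dispersion for both groups. Over 11297 tested genes it recovered 92% of 50 genes raised 1.5-fold, 92% of 50 raised 2-fold and 100% of 50 raised 3-fold. It recovered 78% of 50 lowered to 0.5 of their level and called 12 of 11099 genes simulated without change. In the real data the groups differed in spread and genes shifted together between the controls. The simulation left this out, so its rates need not hold for these data.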

Results

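The transcriptome of AML12 cells, an immortalised mouse hepatocyte line, was measured after transfection with a plasmid carrying Chrna4 or with a GFP control plasmid, in 2 libraries per group. Chrna4 encodes an alpha subunit of neuronal nicotinic acetylcholine receptors, ligand-gated cation channels. The labels state that factors promoting a transition were sought, without naming the transition. Depth was even, from 31301396 to 32228360 reads on listed genes per library. The plasmids differ in more than the Chrna4 insert, and untransfected cells were not analysed here, so each difference is one between 2 transfections. Replicates differed by more than counting noise. The mean chi-square per gene was 14.7 between the controls and 4.17 between the Chrna4 libraries, against 58.1 to 65.6 between libraries of different groups. The typical gene differed less. Its median absolute log2 difference was 0.102 between the controls and 0.0688 between the Chrna4 libraries, against 0.136 to 0.145 between groups. Values are deposited CPM as mean ± SD with n = 2 per group unless stated, folds are ratios of mean CPM, and adjusted p-values are from limma-trend.

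Chrna4 (ENSMUSG00000027577; GRCm38 chromosome 2, 181018380 to 181043546, minus strand, protein-coding) rose from near the limit of detection. It received 1 and 3 reads in the control libraries and 2678 and 2290 reads in the Chrna4 libraries, or 0.0617 ± 0.0438 against 79.8 ± 10.3 CPM (SD, n = 2). The ratio of summed reads, each sum divided by the group's effective library size, was 1291, with an exact 95% interval of 504 to 4742, and the change on the log2(CPM + 1) scale was 6.24 (SE 0.14, adjusted p = 2.30e-10 by limma). On recovered reads, where no pseudocount of 1 is added, the log2 change was 10.25 by edgeR, 10.13 by limma-voom and 10.34 by DESeq2. Reads from the plasmid and from the chromosomal gene cannot be separated. Of 28 nicotinic subunits and cholinergic partners, 10 were listed and 5 tested, and 1, Chrna4, was called, also when adjusted over the list alone. Chrnb1, the muscle-type beta subunit, stood at 26.4 ± 0.127 and 22.2 ± 1.92 CPM (adjusted p = 0.115 by limma). The list, which holds the transfected gene, had a median log2 change of 0.09 and was not past the list test (adjusted p = 0.320 by camera; adjusted p = 0.60 with an estimated correlation). It passed with fry (adjusted p = 0.0297), with Chrna4 as its 1 called member, and by camera without Control 1, without Control 3 and without Chrna4 2.

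In the whole transcriptome 1798 of 11298 tested genes changed, 1046 higher and 752 lower in the Chrna4 libraries. Changes of at least 2-fold on the log2(CPM + 1) scale, which understates the change of low genes, were mostly increases, 157 against 18. The 12 largest increases among genes eligible for naming were those of Chrna4 and 11 others. Ifnb1, which encodes interferon beta (chromosome 4, 88522025 to 88522774), rose from 0.986 ± 0.521 to 9.62 ± 0.182 CPM, 9.75-fold (log2 2.44, SE 0.20, adjusted p = 5.48e-06 by limma). Ifit2, an interferon-induced gene that restrains viral translation (chromosome 19, 34550694 to 34576419), rose from 307 ± 90.4 to 1615 ± 46.8 CPM (log2 2.42, SE 0.14, adjusted p = 5.03e-07 by limma). The chemokine gene Ccl5 rose 4.75-fold, the chemokine-binding receptor gene Ccrl2 5.82-fold, and Ly6a, a cell-surface protein gene, 5.24-fold. The remaining ones were Slfn8 at 7.57-fold, Pyhin1 at 7.17-fold, Phf11b at 6.10-fold, Gbp5 at 5.91-fold, Ifi205 at 5.00-fold and Gvin1 at 4.63-fold. Slfn8, Pyhin1, Phf11b, Gbp5, Ifi205, Gvin1, Ly6a and the Ifit genes have close paralogs. How the authors' counting treated reads that match several of them is not given in the sources used here, so their levels are uncertain.

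The 12 largest decreases were chosen in the same way. Slc16a12, a creatine transporter (chromosome 19, 34668403 to 34747289), fell from 68.3 ± 7.71 to 26.9 ± 2.59 CPM (log2 -1.31, SE 0.10, adjusted p = 2.80e-06 by limma). Alb, encoding serum albumin (chromosome 5, 90460897 to 90476602), fell from 18.4 ± 0.806 to 8.22 ± 0.412 CPM (log2 -1.07, SE 0.11, adjusted p = 4.27e-05 by limma), and Ttr, encoding the thyroid hormone and retinol carrier transthyretin, from 53.3 ± 7.01 to 25.9 ± 2.96 CPM. The signalling ligand gene Wnt4 fell from 72.7 ± 1.27 to 34.1 ± 2.82 CPM and the growth factor receptor gene Fgfr3 from 17.2 ± 1.44 to 8.05 ± 1.26 CPM. The Chrna4 mean was 0.420 of the control mean for the aldolase gene Aldoc, 0.437 for Ncald, 0.440 for the phosphodiesterase gene Pde4c, 0.455 for the retinol-binding protein gene Rbp2, 0.463 for the plasma membrane calcium pump gene Atp2b4, 0.484 for Shank2 and 0.499 for Cmbl. Among changed genes of at least 1.5-fold, those of high level included Rnf213 (3029 ± 152 to 4680 ± 117 CPM), Scd2 (2220 ± 40.3 to 1371 ± 15.6), mt-Nd2 (1441 ± 209.7 to 955 ± 13.6), Irgm1 (796 ± 53.9 to 1284 ± 14.0) and Ifit1 (617 ± 88.3 to 1327 ± 10.9).

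With 1 library left out, each gene's spread was measured only in the other group's pair. The control pair was noisier, with a mean chi-square per gene of 14.7 against 4.17. A call lost or gained in such a fit can therefore reflect that pair's spread and not the library left out. The number of calls changed with the library left out and with the scaling. It was 2916 without Control 1, 3006 without Control 3, 1040 without Chrna4 1 and 928 without Chrna4 2, and with library totals as the scaling 812 genes were higher and 1179 lower, so that 40.8% of calls were increases against 58.2%.

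**Figure D1:**
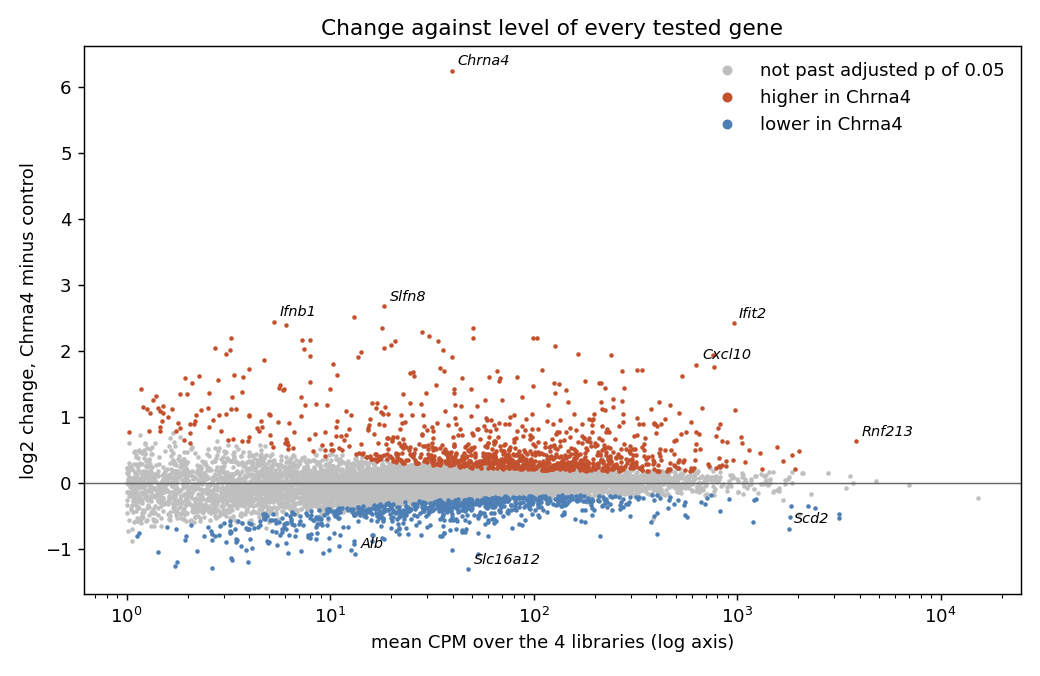
Log2 change (Chrna4 minus control, vertical axis, log2(CPM + 1) scale) against the mean CPM over the 4 libraries (horizontal log axis) for each of 11298 tested genes, coloured where the adjusted p is under 0.05. Chrna4 stands alone at 6.24, and large changes lie mostly above 0, with 157 increases and 18 decreases of at least 2-fold on that scale.

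**Figure D2:**
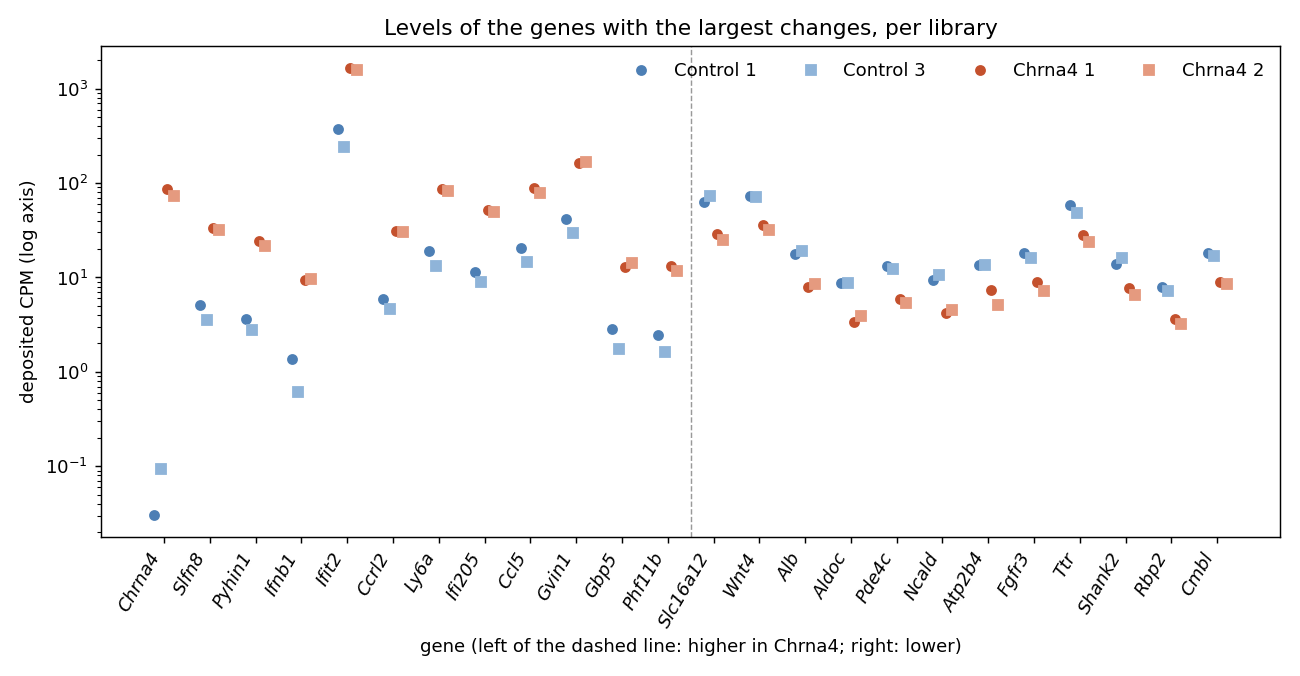
Deposited CPM (vertical log axis) in each of the 4 libraries for the 12 largest increases and the 12 largest decreases (horizontal axis), 1 point per library, circles and squares for the libraries of a group. For each gene both Chrna4 points lie on the same side of both control points, as the rule for naming required.

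Interferon-stimulated genes, the antiviral and signalling genes that interferons induce, rose almost without exception. Of 40 tested, 39 were higher and 0 lower, with a median log2 change of 1.12, and 39 were higher when adjusted over the list alone. Mx1, an antiviral GTPase gene, rose from 99.2 ± 14.0 to 381 ± 7.89 CPM, the chemokine gene Cxcl10 from 284 ± 44.7 to 980 ± 11.1 and Gbp2, from a family of guanylate-binding proteins, from 91.3 ± 10.5 to 267 ± 5.18. The exception, Ifi27, stood at 7.09 ± 1.38 and 5.90 ± 1.54 CPM (adjusted p = 0.422 by limma; chosen after its value was seen). The 14 antigen presentation genes tested all rose, also when adjusted over the list alone (median log2 1.01), among them Nlrc5, the activator of MHC class I genes (40.6 ± 3.57 to 125 ± 2.43 CPM), the peptide transporter genes Tap1 (71.9 ± 9.93 to 164 ± 4.90) and Tap2 (32.1 ± 3.48 to 73.1 ± 4.89), and the immunoproteasome gene Psmb10 (104 ± 11.2 to 214 ± 7.04). Both lists passed the list test (adjusted p = 6.93e-45 and 1.51e-19 by camera) and also passed with fry (adjusted p = 0.0461 and 0.0387). Neither passed with an estimated correlation (adjusted p = 0.397 for each). The control libraries also differed in these genes, with 37 of 40 interferon-stimulated genes and 13 of 14 antigen presentation genes higher in Control 1 than in Control 3, by a median log2 of 0.31 and 0.22.

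Inflammatory genes and NF-kB targets rose as well, 22 of 26 tested, with 1 lower and a median log2 change of 0.77 (24 higher and 1 lower adjusted over the list alone). Tlr2, a receptor for bacterial lipoproteins, rose from 16.6 ± 0.834 to 56.0 ± 0.965 CPM, Csf1, the macrophage growth factor gene, from 230 ± 9.55 to 430 ± 0.0620, and the monocyte chemokine gene Ccl2 from 576 ± 21 to 1067 ± 20.6. The decrease was in the alarmin gene Il33, at a log2 change of -0.56 (adjusted p = 0.000895 by limma; chosen after its value was seen). Of 19 immediate early genes, which respond rapidly to stimulation, 10 rose and 0 fell (median log2 0.36; 10 adjusted over the list alone). They included Egr1 (27.4 ± 2.53 to 54.9 ± 4.91 CPM), Fosl1 (162 ± 6.73 to 240 ± 8.12), Zfp36 (46.6 ± 0.981 to 69.4 ± 2.98) and Dusp5 (46.0 ± 3.69 to 75.2 ± 8.22). The list test gave an adjusted p of 2.95e-20 and 2.42e-07 by camera, and with an estimated correlation an adjusted p of 0.358 for both.

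**Figure D3:**
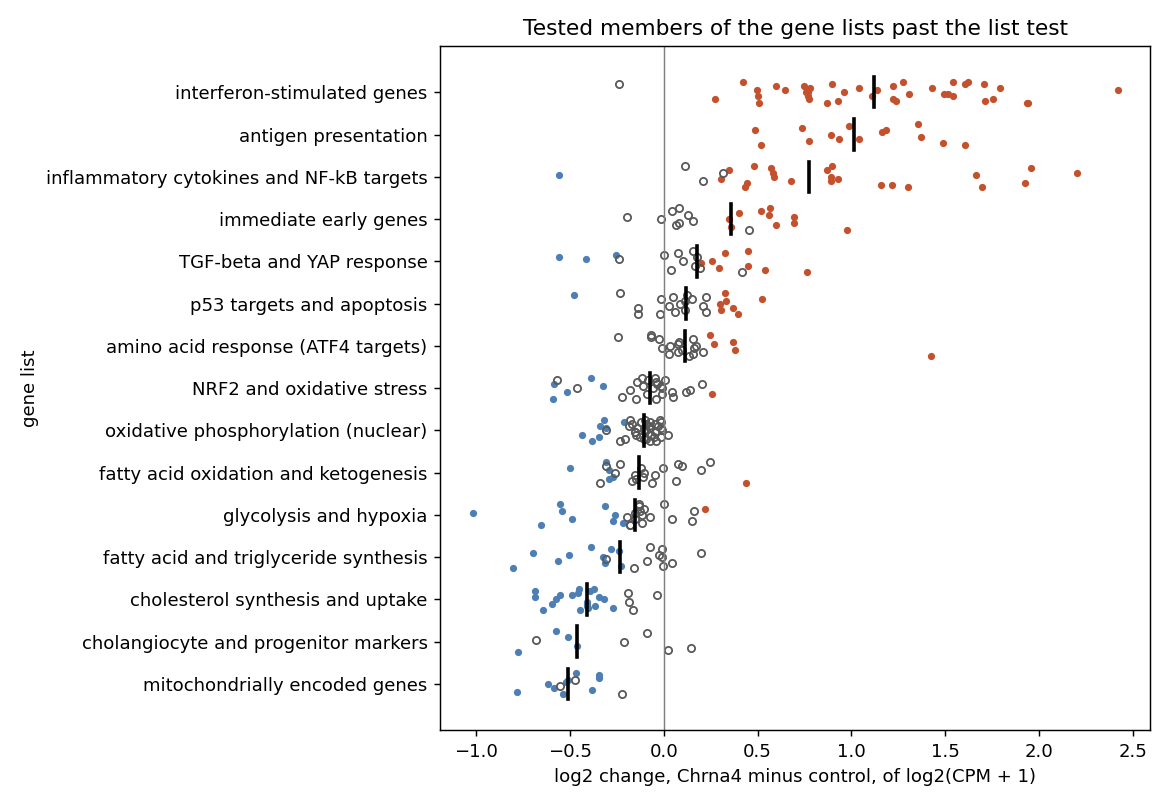
Log2 change (horizontal axis, Chrna4 minus control) of each tested member of the 15 lists past the list test at the preset correlation (vertical axis). Filled points are genes past an adjusted p of 0.05, red higher and blue lower, open points are the others, and black bars are list medians, from 1.12 for interferon-stimulated genes to -0.51 for mitochondrially encoded genes.

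Cholesterol synthesis genes fell together. Of 24 tested, 20 were lower and 0 higher (23 lower adjusted over the list alone), with a median log2 change of -0.41. Sqle, which makes squalene epoxide, fell from 189 ± 10.1 to 129 ± 2.06 CPM, the lanosterol synthase gene Lss from 107 ± 9.61 to 68.1 ± 0.35, Idi1 of the isoprenoid steps from 72.4 ± 1.27 to 47.7 ± 2.50, and Hmgcs1, at the entry of the pathway, from 163 ± 0.274 to 119 ± 3.52. Of 20 genes of fatty acid and triglyceride synthesis, 10 fell and 0 rose (11 adjusted over the list alone; median log2 -0.23). Those that fell included the desaturase genes Scd1 (269 ± 10.0 to 154 ± 0.152 CPM), Scd2 and Fads1 (519 ± 38.7 to 396 ± 5.81) and the elongase gene Elovl6 (55.5 ± 7.04 to 37.0 ± 2.05). Both lists passed the list test (adjusted p = 7.07e-16 and 7.77e-06 by camera), and with an estimated correlation the adjusted p was 0.397 and 0.414. Neither passed with fry (adjusted p = 0.0574 and 0.0691). The control libraries differed in these genes too. Only 3 of 24 in the first list and 4 of 20 in the second were higher in Control 1 than in Control 3. The median log2 difference, Control 1 minus Control 3, was -0.11 for each list. The second list had 5 lower members without Chrna4 1 and 5 without Chrna4 2, and a median of -0.15 without Control 3.

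Fatty acid oxidation moved less evenly, with 5 of 24 tested genes lower and 1 higher (7 and 1 adjusted over the list alone; median log2 -0.13). Of the 5, Etfdh and Eci2 were outside the naming rule and are named after their values were seen, and Hadh and Acaa2 lost the call without Chrna4 1 (adjusted p = 0.236 and 0.0810) and without Chrna4 2 (0.0599 and 0.188). Acadm, the medium-chain acyl-CoA dehydrogenase gene, fell from 67.7 ± 2.71 to 47.6 ± 3.84 CPM, whereas the peroxisomal thiolase gene Acaa1a rose from 109 ± 5.09 to 148 ± 4.0. The list was past the test (adjusted p = 0.0136 by camera), but not with an estimated correlation (adjusted p = 0.397) or with fry (adjusted p = 0.0574). It also did not pass without Control 1, without Control 3 or without Chrna4 1. Without Chrna4 1 or Chrna4 2 it had 1 lower member, against 9 without Control 1 or Control 3, and 2 higher members without Control 1. Among 13 lipid uptake and lipid droplet genes, 3 fell and 1 rose (4 and 1 adjusted over the list alone). The fatty acid binding protein gene Fabp5 fell from 33.1 ± 0.577 to 21.7 ± 1.75 CPM. Hilpda and Plin3 also fell and Plin2, which coats lipid droplets, rose, calls lost without Chrna4 2 (adjusted p = 0.0508, 0.288 and 0.0667) and, for Plin3 and Plin2, without Chrna4 1 (0.0906 and 0.0746). That list did not pass by camera (adjusted p = 0.0605), except without Chrna4 2 and without the filter on low values (adjusted p = 0.0334). It passed as lower with fry (adjusted p = 0.0297). Without Chrna4 2 it had 0 higher and 1 lower members, without Chrna4 1 0 and 2, and without Control 3 2 and 3.

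Transcripts of the mitochondrial genome were lower. Of 13 tested, 10 fell and 0 rose (13 lower adjusted over the list alone), with a median log2 change of -0.51. Their share of reads was 4.08% in Control 1, 3.68% in Control 3, 2.92% in Chrna4 1 and 2.91% in Chrna4 2. The cytochrome b gene mt-Cytb fell from 3760 ± 86.1 to 2593 ± 51.8 CPM, and among complex I subunits mt-Nd4l fell from 350 ± 13.8 to 246 ± 4.1. Unlike most of the 13, both were lower in Control 1 than in Control 3. The complex I gene mt-Nd1 fell from 3684 ± 297 to 2664 ± 38.5 CPM, with 3894 CPM in Control 1 and 3475 in Control 3. The median was -0.27 without Control 1, and 11 of the 13 transcripts were higher in Control 1 than in Control 3. The mean log2 change of the list was -0.49, and -0.37 after the GC content and length correction. Of 41 nuclear genes of oxidative phosphorylation, 7 fell and 0 rose (7 adjusted over the list alone; median log2 -0.10), among them Cox6b1 (107 ± 0.338 to 82.3 ± 1.67 CPM) and Cox7b (144 ± 6.91 to 113 ± 0.976). The median was -0.07 without Control 1, and the number lower was 11 without Control 1, 16 without Control 3, 5 without Chrna4 1 and 2 without Chrna4 2. With library totals 12 were lower and the median was -0.16, and after the GC content and length correction it was -0.07. The lists gave an adjusted p of 1.60e-09 and 2.62e-05 by camera, and of 0.397 and 0.418 with an estimated correlation. Neither passed with fry (adjusted p = 0.0781 and 0.135).

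Of 26 glycolysis and hypoxia genes, 9 fell and 1 rose (11 and 2 adjusted over the list alone, median log2 -0.15). The increase was in the hexokinase gene Hk2 (chosen after its value was seen). The Chrna4 libraries differed in this list, with 24 of 26 genes higher in Chrna4 1 than in Chrna4 2, by a median log2 of 0.11. The list mean was -0.28 without Chrna4 1 and -0.14 without Chrna4 2, against -0.21. Genes that fell included the pyruvate dehydrogenase kinase gene Pdk1 (44.2 ± 2.94 to 27.8 ± 2.02 CPM), the prolyl hydroxylase gene Egln3 (74.1 ± 4.56 to 50.6 ± 1.63) and Ndrg1 (648 ± 8.35 to 464 ± 55.5). Among 30 NRF2 and oxidative stress genes, 5 fell and 1 rose, also when adjusted over the list alone (median log2 -0.07). The increase was in G6pdx, of the pentose phosphate pathway (chosen after its value was seen). The decreases included the glutathione transferase genes Gsta3 (452 ± 29.7 to 299.95 ± 20.1 CPM) and Gsta4 (125 ± 13.9 to 86.9 ± 1.65) and the metallothionein gene Mt1 (205 ± 14.5 to 137 ± 18.0). The lists passed (adjusted p = 4.23e-05 and 0.0103 by camera). Neither passed with an estimated correlation (adjusted p = 0.463 and 0.60) or with fry (adjusted p = 0.135 and 0.283). The second also did not pass without Control 1. The mean of the second was -0.06 without Control 1 and -0.21 without Control 3, against -0.13, and 27 of its 30 genes were higher in Control 1 than in Control 3. The first list had 2 higher and 10 lower members without Control 1, 3 and 17 without Control 3, 0 and 8 without Chrna4 1, 0 and 4 without Chrna4 2, and 0 and 13 with library totals. The second had 4 and 6 without Control 1, 2 and 14 without Control 3, 0 and 6 without Chrna4 1, and 0 and 4 without Chrna4 2. Its median was -0.12 with library totals, and 8 members were lower after the GC content and length correction.

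Markers of bile duct and progenitor cells fell in part, 4 of 9 tested with 0 higher (5 adjusted over the list alone; median log2 -0.46). Krt19 fell from 512 ± 29.0 to 299 ± 1.63 CPM and Krt7 from 50.5 ± 2.78 to 33.6 ± 1.86. The osteopontin gene Spp1 fell from 459 ± 21.3 to 322 ± 0.483 CPM and Cd24a from 468 ± 4.60 to 340 ± 5.92. The list passed by camera (adjusted p = 0.000520), but not with an estimated correlation (adjusted p = 0.414) or with fry (adjusted p = 0.0574). Of 38 hepatocyte function genes 21 were listed and 13 tested, and 3 fell and 0 rose, also when adjusted over the list alone, namely Alb, Ttr and the apolipoprotein gene Apoe (7.74 ± 0.985 to 4.35 ± 0.467 CPM). The median log2 change of that list was 0.05 and its mean -0.18, with opposite signs. It did not pass by camera (adjusted p = 0.195), except without Chrna4 2, but passed as lower with fry (adjusted p = 0.0297). That median was -0.00170 without Control 1 and 0.00496 without Control 3, with 1 gene higher each time. Among 11 epithelial and mesenchymal identity genes 2 fell, Krt19 and Krt7, and 1, Zeb1, rose (3 and 1 adjusted over the list alone), a call lost with library totals (adjusted p = 0.0689), without Chrna4 1 (0.214) and without Chrna4 2 (0.141). Krt19 and Krt7 were in both marker lists, and the second list had a median of 0.06 and a mean of -0.11 (adjusted p = 0.445 by camera). With library totals the second list had a median of 0.003 and a mean of -0.16. It had 2 higher and 3 lower members without Control 1 and 3 and 3 without Control 3.

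Of 21 TGF-beta and YAP response genes, 8 rose and 3 fell (9 and 3 adjusted over the list alone; median log2 0.18). The transcription factor gene Snai2 rose from 36.9 ± 4.19 to 63.0 ± 0.325 CPM, the receptor kinase gene Axl from 1097 ± 47.9 to 1498 ± 41.5 and Ankrd1 from 151 ± 6.79 to 207 ± 7.46, while Id2 fell from 108 ± 3.76 to 72.8 ± 0.670. The list passed (adjusted p = 0.0106 by camera), but not with an estimated correlation (adjusted p = 0.412) or with fry (adjusted p = 0.0691). It also did not pass without Control 1 or without Chrna4 2. Its mean was 0.10 with library totals, against 0.15. Among 14 matrix and fibrogenesis genes 3 rose and 1 fell, also when adjusted over the list alone, including the collagenase gene Mmp13 (50.5 ± 5.95 to 94.5 ± 5.05 CPM) and Timp2 (359 ± 28.3 to 478 ± 15.0), with Spp1, also a bile duct marker here, lower (list adjusted p = 0.453 by camera). The third gene that rose, Thbs1, lost the call without Chrna4 2 (adjusted p = 0.259). The matrix list had 3 higher and 4 lower members without Control 1, 5 and 1 without Control 3, and 3 and 2 with library totals.

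Markers of other liver cell types were mostly below the filter. Of 15 stellate cell and fibroblast markers 2 were listed and 1 tested, Vim, at 1327 ± 36.8 and 1441 ± 0.0287 CPM (adjusted p = 0.194 by limma), which passed without Control 1 (0.00103). Of 15 macrophage markers 3 were listed and 2 tested, Cd14 at 90.8 ± 4.29 and 94.9 ± 2.98 CPM (adjusted p = 0.573) and Cd68 at 4.67 ± 0.665 and 3.99 ± 0.492 CPM (adjusted p = 0.506 by limma). Of 13 endothelial markers 5 were listed and 2 tested. Flt1 fell from 25.6 ± 1.39 to 18.5 ± 1.55 CPM (adjusted p = 0.00981 by limma), a call lost without Chrna4 2 (0.105), and Stab1 stood at 13.0 ± 5.16 and 14.7 ± 0.654 CPM (adjusted p = 0.520), passing as higher without Control 3 (0.000348). Of 12 lymphocyte markers 1 was listed, Cd79a, at 0.185 ± 0.130 and 0.0488 ± 0.0690 CPM, and 0 were tested. Flt1 was also the 1 call in these lists when adjusted over the list alone.

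Of 22 amino acid response genes, targets of ATF4, 5 rose and 0 fell (6 and 1 adjusted over the list alone; median log2 0.12), led by Cebpb, a transcription factor also active in inflammation, from 26.4 ± 4.96 to 72.5 ± 13.1 CPM. Of 24 p53 targets and apoptosis genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; median log2 0.12), including Plk2 (230 ± 16.3 to 302 ± 10.6 CPM) and the death receptor gene Fas (18.4 ± 0.219 to 27.0 ± 1.58). These lists passed (adjusted p = 0.00643 and 0.00668 by camera), with an adjusted p of 0.397 and 0.418 with an estimated correlation. With fry the first passed (adjusted p = 0.0387) and the second did not (adjusted p = 0.133). The second did not pass without Control 3 (0.242), and its mean was 0.08 without Control 3 and 0.07 with library totals, against 0.12. Sesn2 was in both lists, and the p53 target that fell was Sesn1 (chosen after its value was seen). The number higher in the first was 11 without Control 1, 8 without Control 3, 2 without Chrna4 1 and 3 without Chrna4 2. With library totals the first list had 4 higher and 1 lower members and a median of 0.06. After the GC content and length correction 8 of its members were higher. The second list had 12 higher and 0 lower members without Control 1, 9 and 3 without Control 3, 2 and 0 without Chrna4 1, 5 and 0 without Chrna4 2, and 6 and 3 with library totals. Of 25 unfolded protein response genes 3 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of -0.02, a mean of 0.01 and a test pointing lower (adjusted p = 0.839 by camera). Trib3, Syvn1 and Ddit3 rose and Herpud1 fell, calls lost without Chrna4 1 (adjusted p = 0.124, 0.136, 0.0691 and 0.228) and, for Ddit3 and Herpud1, without Chrna4 2 (0.0569 and 0.379). The change of Ddit3 was 0.20 without Control 3, against 0.33. The unfolded protein response list had 4 higher and 3 lower members without Control 1, 4 and 4 without Control 3, 0 and 0 without Chrna4 1, 3 and 0 without Chrna4 2, and 3 and 2 with library totals. Of 16 heat shock genes 2, Hsf1 and Dnajb4, rose (1 adjusted over the list alone; list adjusted p = 0.0631 by camera), and the list passed without the filter on low values (0.0488) and after a correction for GC content and length (0.0445). The number of heat shock genes higher was 6 without Control 1, 3 without Control 3, and 0 without Chrna4 1 or Chrna4 2. Dnajb4 also lost the call with library totals (adjusted p = 0.0846), without the filter (0.0613), after the GC content and length correction (0.0537) and with DESeq2 (0.0872).

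Growth and housekeeping lists were not past the list test. Of 36 cell cycle genes 5 rose and 0 fell, also when adjusted over the list alone, including the kinetochore motor gene Cenpe (98.3 ± 3.61 to 132 ± 4.05 CPM) and the replicative helicase gene Mcm6 (314 ± 4.13 to 403 ± 11.8), with a list adjusted p of 0.0729 by camera. The number higher was 9 without Control 1, 9 without Control 3, 2 without Chrna4 1, 3 without Chrna4 2 and 3 with library totals. Of 26 calcium handling genes 1 rose and 1 fell, and 0 in either direction when adjusted over the list alone (list adjusted p = 0.504 by camera). The increase was in Atp2a2, the endoplasmic reticulum calcium pump gene (549 ± 20.6 to 623 ± 4.69 CPM, adjusted p = 0.0446 by limma). Its call was lost without Chrna4 1 (0.413), without Chrna4 2 (0.381), without the filter on low values (0.0599), with library totals (0.132) and with edgeR without robust estimation (0.0519). The calcium list had 1 higher and 2 lower members without Control 1, 4 and 2 without Control 3, 0 and 1 without Chrna4 1, 0 and 0 without Chrna4 2, 0 and 1 with library totals, and 2 and 3 after the GC content and length correction. Of 52 tested cytosolic ribosomal protein genes 0 rose and 1 fell, and 0 when adjusted over the list alone, with a median of 0.00 and a mean of -0.01. Rpl4 stood at 1359 ± 24.7 and 1407 ± 0.569 CPM and Rpl8 at 1158 ± 73.0 and 1136 ± 24.2 (list adjusted p = 0.678 by camera), and that list passed without Control 3 (0.0279), when 2 members were higher and 8 lower. Without Control 1 there were 2 and 2. In these genes too the controls differed, with 48 of 52 higher in Control 1 than in Control 3. Of 5 tested replication-dependent histone genes 1, Hist1h1d, rose, a gene chosen after its value was seen (2 adjusted over the list alone; list adjusted p = 0.118 by camera, and 0.0423 without Chrna4 2), with Hist1h1c at 25.8 ± 4.50 and 32.8 ± 0.482 CPM (adjusted p = 0.0511 by limma). Hist1h1c passed without Control 1 (4.41e-06), after the GC content and length correction (0.0184) and with limma-voom (0.0495). The number of histone genes higher was 2 without Control 1 and 0 without Control 3, Chrna4 1 or Chrna4 2.

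The authors' deposited table held 2261 genes past an adjusted p of 0.05, 1240 higher and 1021 lower in the Chrna4 libraries. All 1798 genes called by limma-trend were among them in the same direction, 79.5% of the calls in the authors' deposited table. Of the calls in the authors' deposited table that limma-trend did not make, 311 were tested and 152 fell below the filter on low values.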

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

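The correction for GC content and length, the robust edgeR test and the pseudocount of 0.1 for the lists were chosen after the data had been seen. No paired analysis was possible because the groups share only replicate number 1. The Chrna4 transcript stayed past the threshold in all 14 alternative settings. Across scaling, filter, pseudocount, GC and test alternatives the number of changed genes lay between 1562 (DESeq2, with 781 adjusted p left NA) and 2322 (GC content and length), with 1839 for edgeR on recovered reads, of which 1777 were among the 1798. With library totals 1179 genes were lower, against 752, with the median of all genes at -0.05. Leaving out 1 library gave 928 to 3006 changed genes, 604 to 1712 higher and 324 to 1296 lower; the group left with 1 library was assumed to vary like the other, and 909 to 1719 of the 1798 were kept. An adjusted p under 0.01 left 963 genes, 670 higher and 293 lower. A change of at least 2-fold on the log2(CPM + 1) scale left 175, 157 higher and 18 lower. Of these 175 were also 2-fold in the authors' deposited table. Of 26 tested lists 15 passed at the preset correlation. Of these, 10 did not pass with fry, which 8 lists passed in all. With an estimated correlation 0 passed, the smallest adjusted p was 0.358 by camera and 2 lists had an unadjusted p under 0.05. That version of the test rests on 2 residual degrees of freedom. For the immediate early list the estimated correlation was -0.000593, below the preset 0.01, yet its unadjusted p by camera rose from 5.58e-08 to 0.0275. The failures with an estimated correlation therefore cannot be read as the effect of correlated genes alone. Results that changed sign were all uncalled over the 4 libraries, though without Control 3 Stab1 and the ribosomal list passed. The mean log2 change of the unfolded protein response list was -0.0420 with library totals and -0.0118 (without Control 3) to 0.0347 with 1 library left out, of the calcium list 0.00118 at a minimum of 5 CPM, and of the ribosomal list -0.0770 to 0.0591 (without Control 1) with 1 library left out and 0.0198 after the GC and length correction. With 1 library left out Stab1 was -0.175 to 0.592, Rpl8 -0.0912 to 0.0373 and Hist1h2bc -0.00915 to 0.205, Rpl4 was -0.00391 with library totals and Rpl8 0.0365 after the GC and length correction; the cause was not tested. Over the named genes 1544 gene and setting combinations kept direction and call, 55 lost the call, 5 gained it and 5 changed sign, and for lists the numbers were 259, 32, 13 and 6. At 31301396 to 32228360 reads per library, 1 read was worth 0.0308 to 0.0325 CPM, and genes under a mean of 1 CPM were not tested.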

Other observations

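The symbol-stem tests, the test on plasmid DNA and the GC content correction were chosen after the data had been seen, as were the genes named here. Among type I interferon genes beyond Ifnb1, which were not tested as a set, Ifna4 and Ifna2 had higher values in the Chrna4 libraries. Ifna4 rose from 0.524 ± 0.130 to 5.99 ± 0.771 CPM (SD, n = 2; log2 2.20, adjusted p = 1.03e-05 by limma). Ifna2, below the filter and untested, stood at 0.0308 CPM, or 1 read, in each control library and at 0.780 and 0.760 CPM in the Chrna4 libraries. Interferon alpha genes are near-identical, so the member is uncertain. Tlr3, a sensor of double-stranded RNA, rose from 142 ± 11.1 to 307 ± 1.73 CPM, Zbp1 from 51.7 ± 12.1 to 169 ± 7.89 and Mb21d1, the DNA sensor cGAS, from 8.38 ± 1.04 to 14.2 ± 1.02. Tmem173, which encodes the cGAS adaptor STING, stood at 1.16 ± 0.0245 and 1.28 ± 0.203 CPM (adjusted p = 0.847 by limma). The caspase gene Casp4 rose from 3.65 ± 0.842 to 12.3 ± 0.548 CPM, Mlkl from 154 ± 12.4 to 281 ± 7.92 and Gsdmd from 233 ± 3.29 to 306 ± 5.73. Cd274, the ligand of an inhibitory T cell receptor, rose from 64.9 ± 7.90 to 186 ± 0.851 CPM, and Cybb, the catalytic subunit of the phagocyte NADPH oxidase, from 111 ± 6.83 to 318 ± 1.20 CPM. Snrpg, a splicing factor gene, rose from 1.31 ± 0.106 to 6.63 ± 0.510 CPM.

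Grouping tested genes by the letters that open their symbols gave 284 stems of at least 6 genes, of which 10 were past an adjusted p of 0.05 by camera at the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.979; 3 stems had an unadjusted p under 0.05). Single-letter stems, which mix unrelated genes, were dropped after a first pass in which 13 of 295 stems had passed. All 10 tested Gbp genes, which encode interferon-induced GTPases, rose (median log2 1.37, adjusted p = 2.78e-13), as did 7 of 12 Parp genes (median log2 0.54, adjusted p = 0.000125). Gbp genes have close paralogs, and Gbp2, Gbp3, Gbp7 and Parp14 are also in the interferon list, so neither result is independent of that list. Of 10 tested Mcm genes 4 rose and 0 fell (median log2 0.19, adjusted p = 0.0160 by camera). Mcm6, Mcm5 and Mcm2 are also in the cell cycle list, which did not pass the list test.

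Interferon-stimulated genes were higher in the Chrna4 libraries (median log2 1.12). The median was 1.12 after removing the trend with GC content and transcript length and 0.97 at its lowest with 1 library left out (Control 3), which argues against either as the whole cause. Transfected DNA can itself induce interferon, and Ifnb1 rose by a log2 of 2.44, but each group received 1 plasmid and the plasmids differ in more than the insert, so a response to the DNA and a response to the CHRNA4 protein cannot be told apart here. A Chrna4-free copy of the same plasmid was not analysed here.

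Cholesterol synthesis genes were lower (median log2 -0.41), and the median was -0.42 after the GC content and length correction, which argues against that trend as the whole cause. A candidate explanation is 25-hydroxycholesterol, a suppressor of sterol synthesis genes made by the interferon-induced enzyme Ch25h. Ch25h rose from 0.617 ± 0.173 to 3.93 ± 0.142 CPM (log2 1.61, SE 0.20, adjusted p = 0.000144 by limma). Of the liver X receptor targets that this sterol also activates 2 were listed and 0 were above the filter, with Abca1 at 0.848 ± 0.151 and 0.852 ± 0.175 CPM and Mylip at 0.539 ± 0.326 and 1.04 ± 0.411 CPM. The rule for reading this test needed them and was altered after its result was seen, and the hypothesis stays open.

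Mitochondrially encoded transcripts were lower (median log2 -0.51). Their mean log2 change was -0.49, and -0.37 after the GC content and length correction, so part of the difference followed that trend. With RLE factors the median was -0.51, and with library totals -0.56. The median of all tested genes was -0.0014 and -0.054 under these scalings, against -0.0028. Shifts this small could not have removed the difference. The values show only that it did not depend on the choice among these scalings. Without Control 1 the median of the mitochondrial transcripts was -0.27, neither clearly kept nor clearly lost. How much of the difference 1 control library carries therefore stays open. In mt-Co2, for example, Control 1 held 2961 CPM and Control 3 1781, against 1706 and 1602 in the Chrna4 libraries. No biological explanation was tested.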
